A study of Homo sapiens with 12 samples.

How the data were processed

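RNA of 12 MDA-MB-231 samples was hybridised to Affymetrix whole-genome arrays with 54675 probe sets, and 62 of these are control probe sets. The labels give 3 groups of 4 replicates, lettered A to D: a hairpin against GFP as control, hairpins against both HIF alpha subunits (shHIF), and Sharp1 overexpression. The labels call the replicates biological and do not say whether they came from separate cultures or transductions, so p-values measure the spread between these arrays. The vector of the Sharp1 cells and any matched empty vector are not given in the sources used here, and the control of both comparisons is the GFP hairpin.

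The deposited values are log2 expression values made with RMA by the submitters, per the submitters' processing notes, which gives background correction, normalization between arrays and 1 value per probe set. The version of RMA is not given in the sources used here. No detection calls or scan dates were used here. RMA values have no count depth, so the number of arrays and the signal over background limit the precision. The median probe set read 5.41 and the median gene 6.59, and the share of genes called in Sharp1 against control was 2.78% in the dimmest decile of expression and 49.9% in decile 8.

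Probe sets were named through the platform annotation, and symbols were checked by gene ID against the gene table of the assembly GCF_000001405.40 GRCh38.p14, used for names and for the order of neighbouring genes only. Of all probe sets, 41097 had 1 gene symbol, of which 41037 matched a gene ID and 0 were renamed, 1801 had several symbols and 11777 were not named. A gene was represented by its probe set with the highest mean over the 12 arrays, which gave 19775 genes, 10523 of them with more than 1 probe set. Probe sets with several symbols or none were left out of the gene tests. Of 328 pairs of a named gene and a comparison, 11 had another probe set of the gene called in the opposite direction.

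The work was done in R 4.3.3 with limma 3.58.1. Linear models with a mean per group were fitted to all 12 arrays, so that the groups share an estimate of the spread per gene, and contrasts were tested after eBayes with trend. P-values were adjusted by Benjamini-Hochberg over 19775 genes within each comparison, and a gene was called at an adjusted p under 0.05. BHLHE41, HIF1A and EPAS1 were also read on every probe set, in a fit over all probe sets. Fold changes are differences of mean log2 values. The comparisons were Sharp1 against control, shHIF against control, and Sharp1 against shHIF.

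The tests, their thresholds, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The genes named in the report are the targeted genes, the 12 largest rises and the 12 largest falls per comparison among called genes whose 4 arrays of one group lie wholly above the 4 of the other, per list up to 2 called members with the largest rise and up to 2 with the largest fall (up to 4 for the HIF target and clock lists), CCNG2, and the 6 genes called higher and the 6 called lower in both comparisons against control with the largest smaller change. A few of these are left out of the text because their calls changed with the settings, and genes in the closing part were chosen afterwards.

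Gene lists numbered 22: HIF pathway components, hypoxia and HIF targets outside glycolysis, glycolysis, a tumour hypoxia signature, circadian clock, bHLH and ID repressors, TGF-beta targets, mesenchymal and invasion genes, epithelial genes, MDA-MB-231 metastasis genes, collagen modification and crosslinking, cell cycle, sterol synthesis, oxidative phosphorylation, interferon-stimulated genes, inflammatory cytokines and NF-kB, ER stress and amino acid response, p53 targets, YAP and TAZ targets, and markers of luminal breast cells, leukocytes and fibroblasts as other cell types. Of 615 entries, 574 had a tested gene and 41 were not analysed here. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over 66 pairs of list and comparison. As alternatives, camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run.

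The fit was tested on simulated data for Sharp1 against control, with 19775 genes of which 200 were changed, 50 at each size. Of those changed by 0.25 on the log2 scale, 38% were called, of those changed by 0.5, 94%, and of those changed by 1 or 2, 100%. There were 7 false calls among 173. A simulated list of lowered genes was called by camera, and 0 of 21 unchanged lists were. The simulated genes were independent of each other, so these lists do not test the preset correlation. In the data far more genes were called than were changed here, so the shares called may not carry over.

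Because both comparisons use the same control arrays, 100 data sets of unchanged groups against those controls were simulated, the controls were split 2 and 2 in all 6 ways, and the overlap of independent lists was computed, also within 20 strata of expression level. The alternatives were centring of each array on its median, cyclic loess, the mean of all probe sets of a gene, all probe sets as separate features, only genes at or above the median probe set (without dim genes), only the pair of groups compared, eBayes without trend or robust, array weights, adjusted p under 0.01, an absolute log2 change of at least 1, the replicate letter as a block, and leaving out each array in turn. The effect of the arrays with low spike-in signal was examined with alternatives chosen after seeing the data.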

Results

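Transcript levels were measured on 12 whole-genome expression arrays of MDA-MB-231, an established human line from a metastatic breast carcinoma. The arrays fell into 3 groups of 4 replicates. Control cells carried a retroviral hairpin against GFP, shHIF cells were depleted of both HIF alpha subunits, and Sharp1 cells overexpressed the transcriptional repressor encoded by BHLHE41. All cells were harvested from normal culture without treatment. The median log2 signal of an array lay between 5.39 and 5.44, and single probe sets spanned 2.23 to 14.8. The lowest correlation between arrays of a group was 0.996, and the highest between arrays of different groups was 0.995. Spike-in transcripts averaged 9.99 on shHIF array A and 10.02 on shHIF array D, against 10.4 to 10.6 on the other 10 arrays. Ribosomal RNA signal was 12.5 on Sharp1 array B and at least 13.7 elsewhere.

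The targeted transcripts were read first, on every probe set. BHLHE41, which encodes Sharp1, rose 40.9-fold in Sharp1 cells on 1 of its 4 probe sets, from 3.89 ± 0.07 in control to 9.24 ± 0.29 (log2, SD, n = 4). limma's adjusted p over all probe sets was 1.39e-19 for that change. A second probe set rose 3.01-fold (log2 1.59, SE 0.14), from 4.42 in control. The probe set brightest in control cells fell by 2.06 on the log2 scale (SE 0.11), from 6.62 ± 0.20 to 4.56 ± 0.16. The readings of 3.89, 4.42 and 4.56 lay below the median probe set (5.41), so the sizes of these 3 changes rest on dim readings. The dimmest differed by -0.13 (adjusted p = 0.442). EPAS1, the gene of HIF2 alpha, fell by 2.85 in shHIF cells on its brightest probe set (SE 0.07), from 9.53 ± 0.06 to 6.68 ± 0.19, which left 13.8% of the control signal. HIF1A, the gene of HIF1 alpha, fell by 0.73 (SE 0.03), from 12.78 ± 0.02 to 12.05 ± 0.05, which left 60.2%. In Sharp1 cells, EPAS1 also fell, by 0.71 (SE 0.07), with 61.1% left, whereas HIF1A differed by 0.09 (adjusted p = 0.0836). In the fit with 1 probe set per gene, that HIF1A difference had an adjusted p of 0.0626, which ranged from 0.0225 to 0.237 over the alternatives. It passed in 8 of them: without shHIF D (0.0468), Sharp1 C (0.0418) or shHIF A and D (0.0278), with A and D as the only shHIF arrays (0.0325), with array centring (0.0398), without dim genes (0.0387), with only the 2 groups compared (0.0225) and with array weights (0.0442). Another 2 EPAS1 probe sets read near 3.2 to 4.0 in every group and were not called. BHLHE41 did not pass the test in shHIF cells on any of its 4 probe sets.

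**Figure D1:**
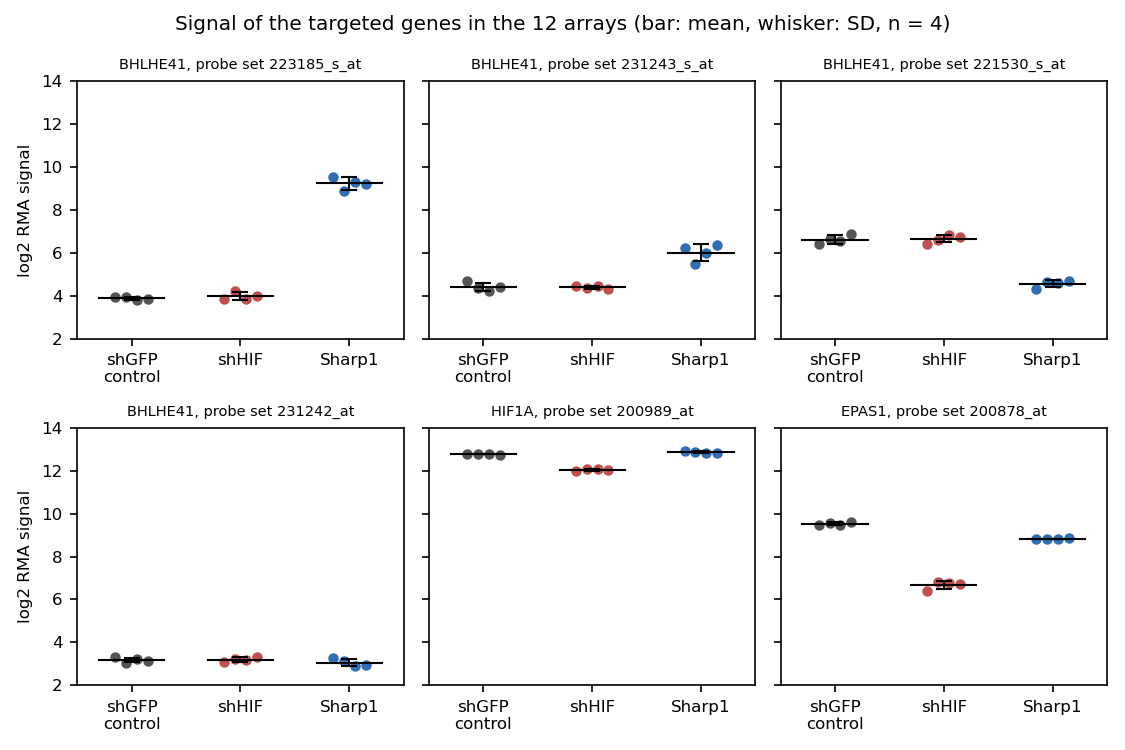
Log2 RMA signal (vertical axis) of 4 BHLHE41 probe sets, 1 HIF1A probe set and 1 EPAS1 probe set in each array of the 3 groups (horizontal axis). Dots are arrays, bars are means and whiskers are SD over 4 arrays. One BHLHE41 probe set rises from 3.89 to 9.24 in Sharp1 cells while another falls from 6.62 to 4.56.

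The first comparison asks which transcripts change when Sharp1 is overexpressed. Compared with the control, Sharp1 cells carried 10.9-fold more DCLK1 mRNA (log2 3.45, SE 0.07, n = 4 per group), which encodes a microtubule-associated kinase. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose 8.71-fold (log2 3.12, SE 0.09), NNMT, which methylates nicotinamide, rose 7.74-fold (log2 2.95, SE 0.07) and INHBE, an activin subunit, rose 6.55-fold (log2 2.71, SE 0.13). ID3, a helix-loop-helix inhibitor of DNA binding, rose 4.75-fold (log2 2.25, SE 0.06). The strongest falls were those of TFF2, a secreted trefoil peptide, which dropped 11.3-fold (log2 -3.49, SE 0.11), and SLAMF7, a receptor known from lymphocytes, which dropped 10.7-fold (log2 -3.42, SE 0.07). The organic anion transporter SLCO4A1 and the secretory-pathway protein AGR2 fell 9.59-fold and 8.08-fold (log2 -3.26, SE 0.05, and -3.01, SE 0.09).

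Other leading rises were SPINK1, a secreted protease inhibitor (log2 2.54), ABI3BP, a matrix protein (2.45), PAPPA, a protease of insulin-like growth factor binding proteins (2.39), and RGS4, a regulator of G protein signalling (2.31). TENM2, CNTN1 and SCN9A, known from neurons, rose by 2.26, 2.19 and 2.14. Other leading falls were NRK, a kinase (-2.92), SLCO4A1-AS1, the antisense transcript of SLCO4A1 (-2.88), RRAGD, a GTPase acting on mTORC1 (-2.71), and TFF1, another trefoil peptide (-2.61). ARMCX1, TGFBI, HES1 and ARHGAP12 fell by 2.46, 2.34, 2.33 and 2.31. HES1 is a Notch-responsive repressor of the same protein class as Sharp1, and TGFBI is a secreted matrix protein. Across 19775 genes, limma called 5370 in Sharp1 cells, 3027 higher and 2343 lower, or 27.2% of those tested. Of these, 141 rose and 192 fell at least 2-fold, and the median size of a called change was 0.31 on the log2 scale. The 4 arrays of one group lay wholly above those of the other for 28.9% of genes, where chance gives 2.86%. INHBE (3.44), SPINK1 (3.64), SCN9A (4.82), COL5A2 (5.01), CNTN1 (5.23) and PTGS2 (5.35) in control, and ST6GALNAC5 (4.28), TNFSF10 (4.37), TFF1 (4.55), LYZ (4.55), IL24 (5.12) and SLAMF7 (5.30) in Sharp1 cells, read below the median probe set (5.41), so the sizes of their changes rest on dim readings.

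Of 50 measured hypoxia and HIF targets outside glycolysis, 21 fell and 8 rose in Sharp1 cells, and 22 and 9 adjusted over the list alone. The list was called lower by camera (adjusted p = 0.00193), a call lost at adjusted p = 0.422 with an estimated correlation. CEMIP, a hyaluronan-degrading protein, fell by 1.99, MXI1, an antagonist of MYC, by 1.86, BNIP3, a mitophagy receptor, by 1.75, and the collagen crosslinker LOXL4 by 1.36. In the other direction, the urokinase receptor PLAUR and the lysyl oxidase LOX rose by 0.81 and 0.80, and PLOD2 and TFRC, a collagen-modifying enzyme and the transferrin receptor, each by 0.53.

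TGF-beta targets rose in Sharp1 cells for 16 of 31 members and fell for 7, or 16 and 8 adjusted over the list alone (camera adjusted p = 0.00285, or adjusted p = 0.422 with an estimated correlation). TAGLN, an actin-binding protein, rose by 1.76 and fibronectin, FN1, by 1.21, while TGFBI and the transcription factor SNAI2 fell by 2.34 and 1.39. The probe sets of FN1, PAPPA and HSP90B1 are of a kind that can bind related transcripts. Of 26 ER stress and amino acid response genes, 17 rose and 4 fell, the same numbers as adjusted over the list alone (adjusted p = 0.00833, or adjusted p = 0.422 with an estimated correlation). CTH and CHAC1, of cysteine and glutathione metabolism, rose by 1.08 and 0.78, and TRIB3 and the chaperone HSP90B1 fell by 0.44 and 0.43. Luminal breast markers, which stood for another cell type, were called lower (adjusted p = 0.0133, or adjusted p = 0.422 with an estimated correlation). Of 15, 5 fell and 2 rose, or 5 and 3 adjusted over the list alone, and AGR2 and TFF1 fell most while XBP1 rose by 0.52. Inflammatory cytokine and NF-kB genes were called higher, with 11 of 30 members up and 4 down by either adjustment, including adjusted over the list alone (adjusted p = 0.0474, or adjusted p = 0.422 with an estimated correlation). PTGS2 and the NF-kB inhibitor TNFAIP3 rose by 3.12 and 1.33, and IL24 and TNFSF10, both cytokines, fell by 2.13 and 1.16. That call was lost without control A or control D (adjusted p = 0.0550 each), Sharp1 C (0.0552) or Sharp1 D (0.0516), with array centring (0.0577) and without dim genes (0.0861), and its adjusted p ranged from 5.98e-06 with fry to 0.422 over all alternatives.

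The remaining 17 lists were not called in Sharp1 cells. Of 30 MDA-MB-231 metastasis genes, 14 rose and 11 fell (adjusted p = 0.0560), among them the sialyltransferase ST6GALNAC5 (-1.82) and the collagenase MMP1 (-1.28). Of 26 collagen and collagen-modifying genes, 10 rose and 5 fell (0.0890), with COL5A2 up by 1.95 and COL6A1 at -1.67. Clock genes were split, 5 higher and 7 lower of 21 (0.523), and PER2, PER3 and BHLHE40 fell by 0.57, 0.52 and 0.51 while RORB and CRY1 rose by 0.73 and 0.33. Of 13 bHLH and ID repressors, 5 rose, led by ID3 and ID4 (1.51), and 3 fell, led by HES1 (0.206). Mesenchymal genes numbered 7 higher and 6 lower of 26 (0.596), with the matrix protein TNC at 1.08 and S100A4 at -1.61, and epithelial genes 4 and 4 of 23 (0.736), with the junction proteins CLDN1 at 1.92 and CLDN4 at -1.22. For glycolysis, 6 of 20 rose and 5 fell (0.826), and the glucose transporter SLC2A3 rose by 0.97. The tumour hypoxia signature had 11 higher and 10 lower of 47 (0.642), HIF pathway components 2 and 2 of 17 (0.716), YAP and TAZ targets 8 and 3 of 17 (0.146), p53 targets 8 and 5 of 19 (0.736), and cell cycle genes 8 and 12 of 42 (0.638). Interferon-stimulated genes numbered 8 higher and 11 lower of 32 (0.206), oxidative phosphorylation 3 and 5 of 42 (0.206), and sterol synthesis 7 and 3 of 18 (0.242). Markers of leukocytes numbered 2 higher and 2 lower of 14 (0.229), with LAPTM5 at -2.18 and LYZ at -1.26, and those of fibroblasts 3 higher and 0 lower of 15 (0.631). Adjusted over the list alone, the counts differed for metastasis genes (15 and 12), collagens (12 and 6), clock genes (6 and 9), mesenchymal genes (9 and 6), glycolysis (7 and 7) and sterol synthesis (8 and 3). Median, mean and test differed in sign for glycolysis (-0.07, 0.05 and lower), epithelial genes (-0.08, 0.01 and lower) and p53 targets (0.03, -0.03 and higher). CCNG2, a cyclin studied with Sharp1 by the same group of authors, fell by 0.36 in Sharp1 cells (SE 0.07, adjusted p = 0.000193), and in shHIF cells it differed by 0.15 (adjusted p = 0.103, or 0.0154 without shHIF A, in a range of 0.00716 to 0.709 over the alternatives). These are values of its brightest probe set. Of its 5 probe sets, 4 were called lower in Sharp1 cells. In shHIF cells the others read 0.08, -0.16, -0.20 and -0.17, and 0 of the 5 were called. The mean of all its probe sets in shHIF was -0.058, so no direction is given for CCNG2 there.

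The next comparison asks what changes when both HIF alpha subunits are depleted. In shHIF cells, besides EPAS1 itself, the glycosyltransferase GXYLT1 fell 4.51-fold (log2 -2.17, SE 0.05, n = 4 per group), the adhesion molecule L1CAM fell 3.77-fold (log2 -1.92, SE 0.08) and TFF2 fell 3.48-fold (log2 -1.80, SE 0.11). The basement membrane collagen COL4A6 rose 4.62-fold (log2 2.21, SE 0.11) and ADTRP, a regulator of tissue factor pathway inhibitor, rose 4.08-fold (log2 2.03, SE 0.12). HLA-DPA1, a chain of MHC class II, rose 3.13-fold (log2 1.65, SE 0.11) and MMP1, which cleaves fibrillar collagen, rose 2.98-fold (log2 1.58, SE 0.09).

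Further rises were those of TMEM132D-AS1 (log2 2.12), the annexin ANXA10 (1.71), the vitamin B12 carrier TCN1 (1.67), the phosphatase PTPRR (1.62), the tight junction protein CLDN1 (1.54), HCP5 (1.53), the cytokine receptor subunit CSF2RB (1.52) and the pseudogene AADACP1 (1.51). Further falls were those of TRNP1 (-1.67), the integrin ITGB2 (-1.64) with its antisense transcript ITGB2-AS1 (-1.62), the RNA-binding protein NANOS1 (-1.51) and S100A2 (-1.49). TMEM30A, a subunit of phospholipid flippases, fell by 1.49, TMEM170B by 1.48 and INSIG1, a regulator of sterol synthesis, by 1.45. limma called 6095 of 19775 genes, 3482 higher and 2613 lower (30.8%), of which 44 rose and 85 fell at least 2-fold. The median change over all genes tested was 0.047. With each array centred on its median, 3049 genes were higher and 2656 lower, so the surplus of rises depends on centring. The median called change was 0.30, and 28.6% of genes had wholly separate groups, against 2.86% by chance. COL4A6 (3.79), CSF2RB (4.13), TMEM132D-AS1 (4.34), HCP5 (4.46), TCN1 (4.56), HLA-DPA1 (4.89) and AADACP1 (4.89) in control, and RORB (4.94), TMEM170B (5.29) and GRHL1 (5.35) in shHIF cells, read below the median probe set (5.41), so the sizes of their changes rest on dim readings. Spike-in signal, a sign of array quality, averaged 10.22 ± 0.25 in shHIF and 10.49 ± 0.05 in control (SD, n = 4, exact two-sided permutation p = 0.0286, adjusted p = 0.343 over 12 such tests). Actin 3′ minus 5′ signal, a sign of RNA quality, averaged 0.84 ± 0.15 in shHIF and 0.68 ± 0.07 in control (permutation p = 0.114, adjusted p = 0.429). It was 0.94, 0.90 and 0.91 on shHIF A, B and C, above every control array (0.59 to 0.74), and 0.62 on shHIF D. Without shHIF A and D, the arrays with low spike-in, a setting chosen after the data were seen, 5060 genes were called, 4589 of them among the 6095.

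Hypoxia and HIF targets outside glycolysis fell in shHIF cells for 21 of 50 members and rose for 7, or 22 and 7 adjusted over the list alone (camera adjusted p = 0.000123, or adjusted p = 0.422 with an estimated correlation). L1CAM led, followed by the transcription factor ZNF395, which fell by 1.27, NDRG1, a hypoxia-induced stress protein, by 1.02, and ANKRD37, by 0.89. TMEM45A and JMJD6 rose by 0.33 and 0.30. P4HA2, a collagen prolyl hydroxylase, read 0.37 on its brightest probe set and -0.25 as the mean of its probe sets. With shHIF B and C alone, whose spike-in was near that of control, 20 of the 50 fell and 8 rose, and with A and D alone 23 fell and 7 rose. The tumour hypoxia signature, which shares 8 genes with that list, fell for 20 of 47 members and rose for 7, or 20 and 10 adjusted over the list alone (adjusted p = 0.00471, or adjusted p = 0.422 with an estimated correlation). The protease CTSV rose against its direction, by 0.81. Glycolysis, which shares 11 genes with the signature, had 8 of 20 members down, led by PGAM1 (-0.44), and 1 up, or 10 and 3 adjusted over the list alone (adjusted p = 0.0199, or adjusted p = 0.446 with an estimated correlation). That call was lost without control D (adjusted p = 0.0550), without dim genes (0.0954) and with shHIF A and D alone (0.0897), within a range of 0.00129 with fry to 0.446 over its alternatives.

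**Figure D2:**
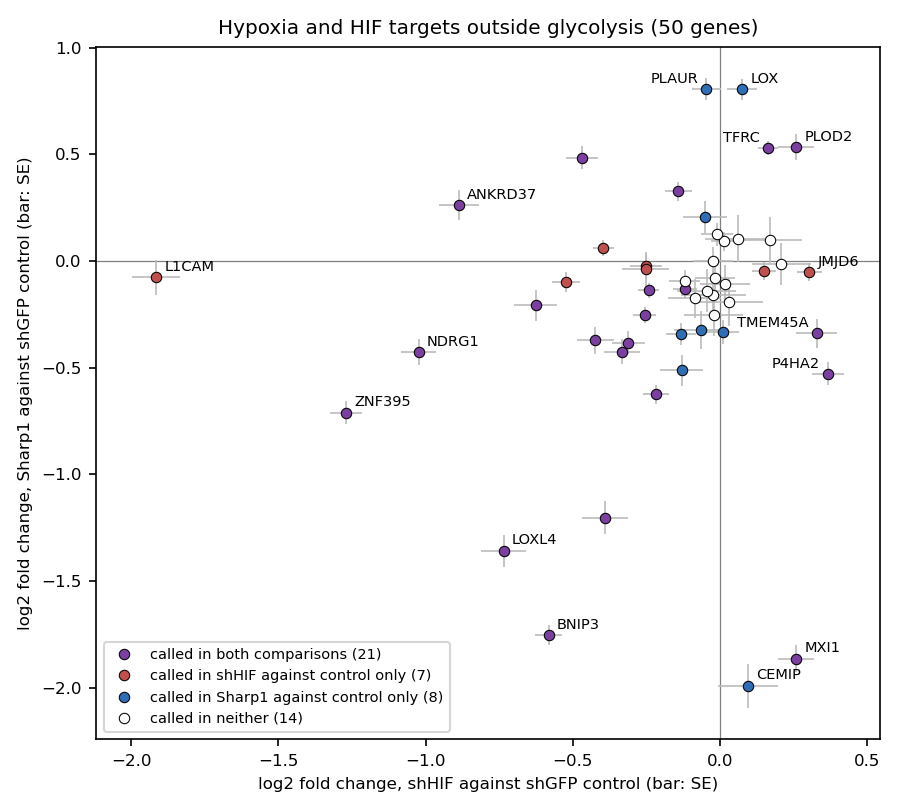
Log2 fold change of 50 hypoxia and HIF targets in shHIF against control (horizontal axis) and in Sharp1 against control (vertical axis), with SE as bars; dot colour gives the comparisons in which a gene was called. Of the 50, 21 were called in both, 7 in shHIF alone, 8 in Sharp1 alone and 14 in neither, and 13 lie among the genes called lower in both.

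Inflammatory cytokine and NF-kB genes rose in shHIF cells for 15 of 30 members and fell for 2, or 16 and 3 adjusted over the list alone (adjusted p = 0.00193, or adjusted p = 0.277 with an estimated correlation). IL24 and IL6, both cytokines, rose by 1.40 and 1.18, while the mitochondrial dismutase SOD2 fell by 0.54. YAP and TAZ targets fell for 9 of 17 and rose for 2, the same as adjusted over the list alone (adjusted p = 0.00285, or adjusted p = 0.422 with an estimated correlation). AJUBA, a LIM protein of the Hippo pathway, fell by 0.82 and the matricellular protein CCN2 by 0.61, and LATS2, a kinase that restrains YAP, rose by 0.42. Epithelial genes fell for 8 of 23 and rose for 1, or 9 and 1 adjusted over the list alone (adjusted p = 0.0141, or adjusted p = 0.277 with an estimated correlation). KRT19 and the transcription factor GRHL1 fell by 1.13 and 0.46 while CLDN1 rose. The epithelial call was lost without dim genes (adjusted p = 0.0910), and its adjusted p was as low as 1.36e-05 with fry and as high as 0.277 with an estimated correlation.

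Another 16 lists were not called in shHIF cells. Clock genes numbered 1 higher and 7 lower of 21 (adjusted p = 0.0610), with the nuclear receptor RORB at -0.74 and NPAS2, a partner of the core clock factors, at -0.23. HIF pathway components numbered 3 higher and 4 lower of 17 (0.0890), with EPAS1 and HIF1A among the falls. Cell cycle genes numbered 12 higher and 5 lower of 42 (0.264), with the cyclin CCNE1 at 1.29, and oxidative phosphorylation genes 14 and 5 of 42 (0.234). Metastasis genes numbered 13 and 8 of 30 (0.888), TGF-beta targets 10 and 5 of 31 (0.937), collagens and their enzymes 9 and 7 of 26 (0.736), with LOXL1 at -1.16, and mesenchymal genes 4 and 7 of 26 (0.463), with the actin bundler FSCN1 at -0.85. ER stress genes numbered 6 and 8 of 26 (0.642), p53 targets 5 and 6 of 19 (0.350), sterol synthesis 5 and 4 of 18 (0.736), bHLH and ID repressors 4 and 2 of 13 (0.578) and interferon-stimulated genes 9 and 6 of 32 (0.695). Luminal markers numbered 2 higher and 5 lower of 15 (0.124), with ERBB3 at -1.19, leukocyte markers 3 and 2 of 14 (0.987) and fibroblast markers 2 and 0 of 15 (0.736). Adjusted over the list alone, the counts differed for metastasis genes (14 and 8), mesenchymal genes (5 and 7), oxidative phosphorylation (15 and 6), bHLH and ID repressors (5 and 2), p53 targets (6 and 6) and luminal markers (2 and 6). Median, mean and test differed in sign for mesenchymal genes (0.03, 0.02 and lower), collagens (0.07, -0.02 and lower), ER stress genes (-0.01, 0.02 and lower), leukocyte markers (0.03, 0.03 and lower) and sterol synthesis (0.0045, -0.03 and lower).

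Sharp1 cells were also set directly against shHIF cells, which tests whether the effects differ. DCLK1 was 15.6-fold higher in Sharp1 cells (log2 3.97, SE 0.07, n = 4 per group), TRNP1, a nuclear protein of neural progenitors, 10.9-fold (log2 3.45, SE 0.07), and ZFPM2, a cofactor of GATA factors, 7.39-fold (log2 2.89, SE 0.09). SLAMF7 was 11.9-fold lower (log2 -3.58, SE 0.07), the cytokine IL24 11.6-fold lower (log2 -3.54, SE 0.08) and AGR2 10.4-fold lower (log2 -3.38, SE 0.09). HLA-DRA and HLA-DPA1, chains of MHC class II, were 8.77-fold and 7.82-fold lower (log2 -3.13, SE 0.15, and -2.97, SE 0.11), and MMP1 7.26-fold lower (log2 -2.86, SE 0.09). EPAS1 and HIF1A, the genes depleted in shHIF, were higher in Sharp1 cells by 2.14 and 0.82.

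Other transcripts higher in Sharp1 cells were PAPPA (log2 2.86), MYCT1 (2.83), PTGS2 (2.70), CNTN1 (2.66), INHBE (2.63), the monoamine oxidase MAOA (2.60), TENM2 (2.56), RGS4 (2.25) and the neural transcription factor POU3F2 (2.25). RRAGD and ADTRP (-3.16 each), TMEM132D-AS1 (-3.04), NRK (-2.79), ST6GALNAC5 (-2.71) and the aldo-keto reductase AKR1C3 (-2.70) were lower. limma called 7588 genes, 3557 higher in Sharp1 and 4031 lower (38.4%), of which 258 and 220 differed at least 2-fold. The median difference over all genes tested was -0.060. The median called difference was 0.33, and 35.4% of genes had wholly separate groups, against 2.86% by chance. TMEM132D-AS1 (3.42), HLA-DPA1 (3.57), ST6GALNAC5 (4.28), ADTRP (4.95), HLA-DRA (5.01), IL24 (5.12) and SLAMF7 (5.30) in Sharp1 cells, and SPP1 (3.31), INHBE (3.52), POU3F2 (4.57), CNTN1 (4.77), ZFPM2 (4.86) and RORB (4.94) in shHIF cells, read below the median probe set (5.41), so the sizes of their differences rest on dim readings. The larger direction turned with centring of each array on its median (3865 higher, 3208 lower) with all probe sets as features (8358 and 7541), at an adjusted p under 0.01 (2963 and 2931) and among differences of at least 2-fold (258 and 220).

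YAP and TAZ targets were higher in Sharp1 than in shHIF cells for 10 of 17 members and lower for 3, the same as adjusted over the list alone (adjusted p = 0.00193, or adjusted p = 0.422 with an estimated correlation). ANKRD1 and CCN2 differed by 1.11 and 0.97, and F3, tissue factor, by -0.35. TGF-beta targets were higher for 16 of 31 and lower for 7, again the same as adjusted over the list alone (adjusted p = 0.00324, or adjusted p = 0.422 with an estimated correlation), with COL4A1 at 1.65, TAGLN at 1.54, TGFBI at -2.48 and SNAI2 at -1.75. Metastasis genes were higher for 15 of 30 and lower for 12, as they were adjusted over the list alone (adjusted p = 0.0254, or adjusted p = 0.422 with an estimated correlation). Among them the secreted SPP1, osteopontin, differed by 1.93 beside PTGS2, and ST6GALNAC5 and MMP1 were lower. The metastasis call was lost with the mean of all probe sets (adjusted p = 0.185) and without dim genes (0.164), within a range of 2.77e-06 with fry to 0.422.

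Hypoxia and HIF targets were split between these groups, 17 higher in Sharp1 and 14 lower of 50 (adjusted p = 0.596). L1CAM, ANKRD37 and VEGFA, the endothelial growth factor, were higher by 1.84, 1.15 and 0.95, and MXI1, CEMIP and BNIP3 differed by -2.12, -2.08 and -1.17. Uncalled lists with the lowest p were ER stress genes, 14 higher and 7 lower of 26 (0.0610), oxidative phosphorylation, 5 and 18 of 42 (0.0890), the tumour hypoxia signature, 14 and 11 of 47 (0.124), and interferon-stimulated genes, 5 and 14 of 32 (0.124). Inflammatory genes numbered 7 higher and 12 lower of 30 (0.596), glycolysis 5 and 3 of 20 (0.146), HIF pathway components 5 and 2 of 17 (0.206) and collagens 9 and 5 of 26 (0.203). Mesenchymal genes numbered 11 and 5 of 26 (0.206), epithelial genes 9 and 4 of 23 (0.206), p53 targets 9 and 5 of 19 (0.206), sterol synthesis 7 and 6 of 18 (0.350), and bHLH and ID repressors 4 and 4 of 13 (0.567). Clock genes numbered 6 and 5 of 21 (0.578), with RORB at 1.47 and PER2 at -0.81, and cell cycle genes 7 and 21 of 42 (0.203). Luminal markers numbered 4 higher and 6 lower of 15 (0.206), leukocyte markers 1 and 4 of 14 (0.229) and fibroblast markers 1 and 0 of 15 (0.831). Adjusted over the list alone, the counts were 18 and 15 for hypoxia and HIF targets, 14 and 9 for ER stress genes, 5 and 20 for oxidative phosphorylation, 8 and 23 for cell cycle genes, 15 and 12 for the tumour hypoxia signature and 10 and 7 for collagens, and equal to those above for the rest. For hypoxia and HIF targets the median (-0.04) and mean (-0.03) lay below 0 and the test pointed higher, and clock genes (median -0.05, mean 0.04, test higher), bHLH and ID repressors (-0.05, 0.10, higher), epithelial genes (-0.02, 0.10, higher) and mesenchymal genes (0.02, -0.01, higher) were also mixed. So were HIF pathway components (-0.0033, 0.19, higher) and fibroblast markers (-0.05, 0.0017, higher).

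**Figure D3:**
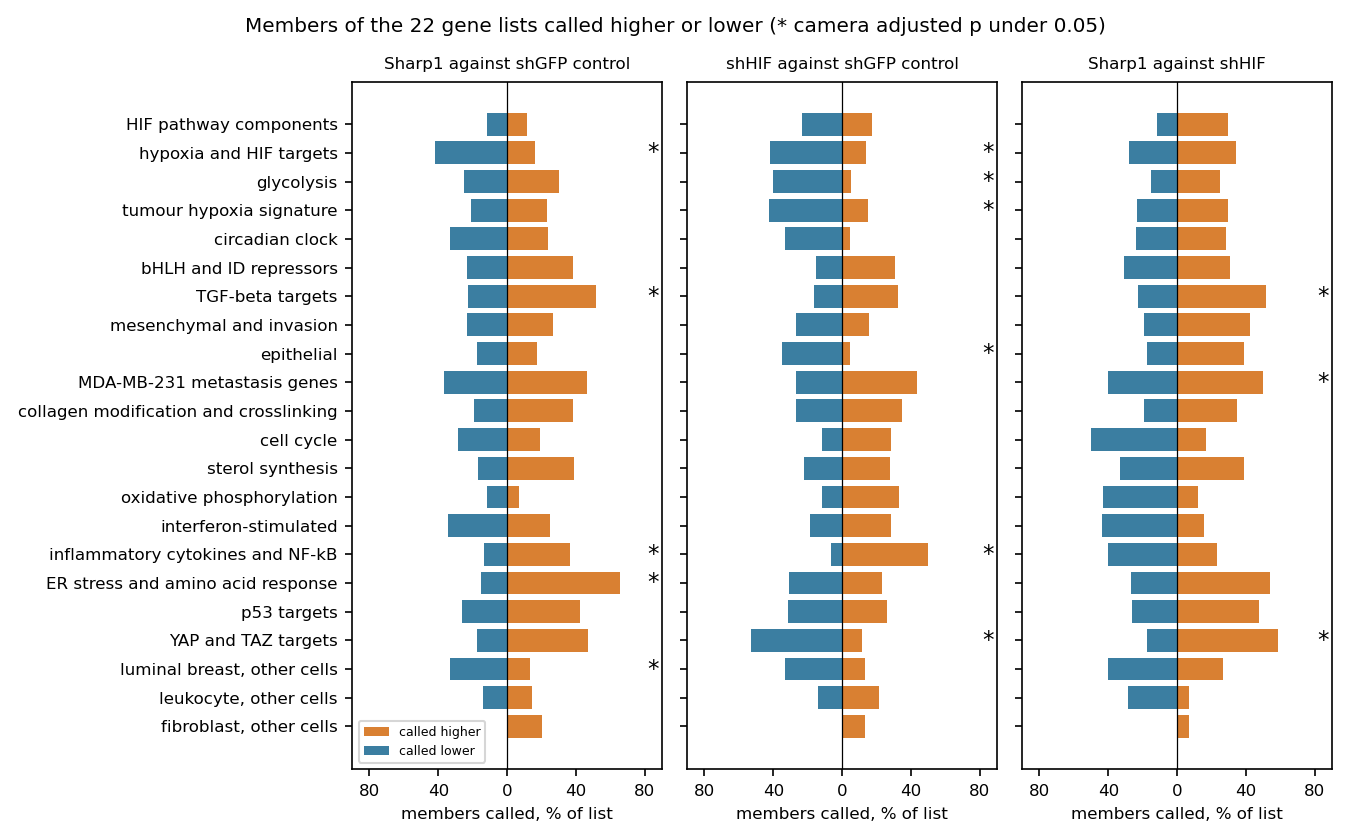
Share of the members of each of 22 gene lists called higher (bars to the right) or lower (bars to the left), in % of the list (horizontal axis), in each comparison; an asterisk marks a list with a camera adjusted p under 0.05. Hypoxia and HIF targets were called lower in Sharp1 (21 of 50 down) and in shHIF (21 of 50 down) against control, and none of the marked lists passed with an estimated correlation.

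Because the study sets Sharp1 overexpression beside HIF depletion, changes against the common control were compared gene by gene. CLDN1 rose in both (1.92 in Sharp1, 1.54 in shHIF), as did AADACP1 (1.94 and 1.51), the cytokine TNFSF15 (1.84 and 1.39), the cyclin CCND2 (1.97 and 1.36), SPINK1 (2.54 and 1.21) and the histone gene H4C8 (1.08 and 1.11). Control signals of SPINK1 (3.64), AADACP1 (4.89) and H4C8 (5.34) lay below the median probe set, as did that of TFF1 in Sharp1 cells (4.55). TFF2 (-3.49 and -1.80), ITGB2 (-2.19 and -1.64), S100A2 (-2.17 and -1.49), INSIG1 (-1.41 and -1.45) and TFF1 (-2.61 and -1.39) fell in both. SLCO4A1 fell by 3.26 in Sharp1 and by 1.25 in shHIF, where another of its probe sets was called in the opposite direction. In all, 1013 genes were called higher in both, against 533 for independent lists, and 700 lower in both, against 310. With independence taken within strata of expression level, the figures were 764 and 474. Simulated unchanged groups against the same controls gave hardly any calls (means of 0 and 0.01 in both), so they do not measure what sharing the controls adds to these counts. When the controls were split 2 and 2 so that no array was shared, 627 to 699 genes were higher in both and 471 to 493 lower in both, against means of 312 and 198 for independent lists of those sizes. Those means were not taken within level strata, which raised the expected counts with shared controls. The size of the excess with split controls is thus not corrected for expression level. Genes moving in opposite directions numbered 529 lower in Sharp1 and higher in shHIF, and 632 the other way, against 413 and 400.0 for independent lists, and 575 and 634 within level strata. With split controls they averaged 355 and 440, against 249 and 252, so an excess over independent lists without strata was not limited to genes moving the same way.

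Across genes, the log2 fold changes had a Pearson r of 0.130 and a Spearman rho of 0.178, against 0.499 and 0.472 for simulated unchanged groups that shared the controls. No gene is changed in that simulation, so the shared controls alone set its r and rho. In the data changed genes widen the fold changes, so the observed r and rho are not comparable in size with the simulated ones. The covariance was 0.00955 against 0.00360 in the simulation, a difference of 0.00595, and with split controls it averaged 0.00615, while r lay between 0.0493 and 0.109. Spearman rho averaged 0.0576 with split controls (0.0042 to 0.105), beside 0.178 with shared controls. The share of genes with the same sign averaged 51.4% (48.6% to 54.3%), beside 56.3% with shared controls. Each comparison then also has fewer controls, which adds noise, so the drops in r, rho and this share cannot be credited to sharing alone. For the covariance, the difference from the simulation (0.00595) lay close to the split-control mean (0.00615, range 0.00391 to 0.00814). Sharing alone could thus account for the drop of the covariance. Genes are not independent replicates, so no p is attached. Of the hypoxia and HIF targets, 13 fell in both, where 8.82 are expected from the 2 counts. With split controls, 11 or 12 did, against 6.46 to 7.56 expected. BNIP3 and LOXL4 fell in both comparisons, NDRG1 and ZNF395 likewise, whereas MXI1 fell in Sharp1 and rose by 0.26 in shHIF. For the tumour hypoxia signature, 9 fell in both against 4.26 expected, and 7 or 8 with split controls, against 3.40 to 4.21. Neither excess is given a test here, since the comparisons share controls, genes are not independent and the expected counts ignore expression level. All genes also showed an excess, with 700 lower in both against 310 for independent lists, or 474 within level strata. An excess is thus not particular to these lists. None of the calls among the 22 lists held with an estimated correlation.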

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

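The tests on BHLHE41 probe sets and on MHC class II genes, and the lists of MHC genes, were chosen after the results were seen. Of 684 groups of 4 values examined, 29 held an array whose gap to its neighbour, as a share of the group's range, passed the critical Dixon ratio for 4 values, and chance gives about 1 in 20 such groups. The counts of called genes were set against all 35 splits of the 8 arrays compared. In each comparison only 1 of the 35 splits, the real one, called as many genes (5370 for Sharp1, 6095 for shHIF and 7588 for Sharp1 against shHIF), and the highest other split called 0 with limma. Every other split mixes arrays of both groups, so the difference between the groups counts as spread and few calls follow. The splits therefore do not tell what set the groups apart.

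BHLHE41 probe sets moved in opposite directions in Sharp1 arrays. Mislabelled Sharp1 arrays are argued against by the most raised probe set, whose lowest Sharp1 array lay 4.91 above its highest control array. A reading of background alone by the falling probe set is argued against by its control mean, 1.21 above the median probe set, with a fall of 2.06 (SE 0.11). That the falling probe set may read only the cells' own transcript, and the others the introduced sequence, stays open, because neither the probe nor the construct sequences are at hand. If it reads only the cells' own transcript, its change of -2.06 is a lower level of that transcript, since probe placement alone would leave it unchanged. Why that level would be lower was not tested.

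On shHIF arrays A and D, spike-in transcripts were low, averaging 10.01 over both, and 430 genes were called between them and B and C, 366 of them lower in A and D. A candidate explanation for the fall of hypoxia and HIF targets in shHIF, these arrays alone, is argued against: without them the list's mean change was -0.16, beside -0.19 with all 4, and camera's p was 2.21e-05 at the preset correlation (with all 4 arrays and an estimated correlation the list's adjusted p = 0.422). Fold changes in shHIF were also shared between genes 50 neighbours apart in genome order, with a rank correlation of 0.0479 across genes (SD of shuffled orders 0.00936), which was -0.0023 in Sharp1. With B and C alone it was 0.030, just above the shuffled maximum of 0.0284, and 0.0770, 0.0457 and 0.0376 at 1, 5 and 20 neighbours, while the difference between A and D and B and C gave 0.0878, 0.0758 and 0.0559 there and 0.0074 at 50 (shuffled maximum 0.0232). A shared signal is thus present without the low arrays, but 0.030 lies between the values that would decide, so how much comes from the low arrays cannot be told. No other source of the shared signal was tested.

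Of 11 MHC class II genes, 7 were lower in Sharp1 and 7 higher in shHIF, while HLA-DOA, HLA-DQA1 and HLA-DQB1 were called in neither. Leukocyte RNA as the source is argued against in part by the leukocyte list, whose median difference between Sharp1 and shHIF was -0.12 (interquartile range 0.27) beside -1.19 for class II genes. Of its 14 members, 9 were not called, 4 were lower and 1 was higher in Sharp1, and LAPTM5, at a control mean of 9.04, differed by -2.01. A median over mostly uncalled members cannot exclude such RNA. CD74, which has no HLA paralogue, differed by -2.54, so the pattern is not carried by HLA probe sets alone. Its change cannot show whether HLA probe sets read each other's transcripts, so cross-hybridisation between HLA paralogues stays open. Whether a changed level of CIITA, the class II transactivator, could account for the pattern stays open. Between Sharp1 and shHIF it differed by -0.26 (limma's adjusted p = 0.0503), at a signal near the median probe set. Against control it was called in neither comparison, at -0.08 in Sharp1 (adjusted p = 0.673) and 0.18 in shHIF (adjusted p = 0.206).

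The remaining values are ratios of the outlying array's gap to the range of its group. In control, GDF15 (0.899), ANKRD1 (0.844), ANXA10 (0.945), ADAM19 (0.852), JUNB (0.877) and MSMO1 (0.836) stood apart in array D, CDC6 (0.905), FSCN1 (0.911) and SDHC (0.880) in B, and PER2 (0.862) and ATF3 (0.961) in C. In Sharp1 array B, PFKP (0.940), BHLHE40 (0.895), KRT7 (0.835), KRT19 (0.853) and TRNP1 (0.897) did, together with ribosomal RNA (0.935), which read 12.5 there and 13.8 on average in the others. IFI27 (0.863), AADACP1 (0.840), ANKRD37 (0.951) and HMGCS1 (0.874) stood apart in Sharp1 array A, and SCN9A (0.859) and LCP2 (0.864) in Sharp1 D. In shHIF, MXI1 (0.900) and IRF9 (0.865) stood apart in array A, ID3 (0.870) and COL3A1 (0.847) in B, COL5A2 (0.867) in C, and the ratio of actin 3′ to 5′ signal (0.860) in D. Among 13522 probe sets without a single gene name, which no comparison of genes uses, 1294 were called in Sharp1 and 1869 in shHIF against control.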

How the results depend on the processing

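The settings that leave out or keep only shHIF A and D, and the lists under array centring and without dim genes, were chosen after the results were seen. Of the alternative values for the counts, overlaps and targeted genes, 266 kept their direction and side of the threshold or stayed within their limits. Another 31 moved, 1 was reversed and 1 lost its call. Of the list values 268 kept theirs and 26 lost a call, and 8109 values for named genes kept theirs. Some values could not change: array centring, other eBayes settings, other thresholds and the replicate block leave the correlation of fold changes as it is. Named genes lost a call 297 times, 174 of them when a change of at least 1 was required, which by construction removes smaller changes, and 10 times gained one. Low signal limits what can be seen: in the dimmest decile of expression 2.78%, 3.13% and 4.50% of genes were called in the 3 comparisons. An absolute log2 change of at least 1 left 333 genes in Sharp1, 129 in shHIF and 478 between them, 12 higher and 13 lower in both, and not HIF1A, at -0.73. All probe sets as separate features gave 9875, 12122 and 15899 called and 1347 lower in both, since more features were tested. The larger direction turned with all probe sets in shHIF (5861 higher, 6261 lower, beside 3482 and 2613) and between Sharp1 and shHIF (8358 and 7541, beside 3557 and 4031), and there also with array centring (3865 and 3208) and at an adjusted p under 0.01 (2963 and 2931). It turned in all 3 comparisons when a change of at least 1 was required (141 and 192 in Sharp1, beside 3027 and 2343, 44 and 85 in shHIF, 258 and 220 between them). The cause was not tested. An adjusted p under 0.01 gave 658 higher in both. The mean of all probe sets of a gene turned BHLHE41 to 1.19 in Sharp1, since it averages rising and falling probe sets, and turned COX7B in Sharp1 to 0.27 and, in shHIF, P4HA2 to -0.25, SDHC to -0.10, CCNG2 to -0.058 and CCNA2 to 0.10; the cause was not tested. With an estimated correlation 0 lists were called by camera, against 14 at the preset one and 41 by fry, which does not compare a list with other genes. The correlation of fold changes was 0.149 with the mean of all probe sets, 0.114 without dim genes, 0.113 to 0.156 when an array was left out, 0.144 without shHIF A and D and 0.106 with these alone; the cause was not tested. With the controls split it was 0.109, 0.0493, 0.0729, 0.0868, 0.104 and 0.0605, and 665, 675, 627, 634 and 630 genes were higher in both in the splits that moved, where each comparison had fewer controls. Leaving out an array gave 4770 to 5644 calls in Sharp1, 5142 to 6402 in shHIF and 6849 to 7851 between them. With the replicate block, the counts were 5186, 5897 and 7373, with 14 lists, and no named gene or list changed its call. Same-letter arrays did not deviate together: their deviations correlated at -0.18 to 0.024, -0.17 to 0.039 and -0.11 to 0.14, 1 of 12 pairs exceeded 0.1, and of 24 best matches, each array being set against both other groups, 2 were with its own letter.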

Other observations

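The gene lists in this part were drawn up after the results were seen, around genes already found among the largest changes, so their counts describe and no test of a list is given. Several genes of MHC class II presentation, which shows peptides to helper T cells, moved in opposite directions in the perturbed groups. Of 11 measured, 7 fell and 0 rose in Sharp1 cells, and 7 rose and 0 fell in shHIF cells. HLA-DRA fell by 1.79 in Sharp1 and rose by 1.34 in shHIF, and CD74, the invariant chain, fell by 1.84 and rose by 0.70. Class I presentation, with 12 genes measured, fell for 7 and rose for 0 in Sharp1 cells. The falls were mostly small: PSMB9 fell by 1.13 and PSMB8 by 0.43, but HLA-B, HLA-C, HLA-F, B2M and TAP2 by only 0.14 to 0.18. In shHIF cells 11 rose, with HLA-B up by 0.96 and the immunoproteasome subunit PSMB9 by 0.53, and only the transporter subunit TAP2 fell, by 0.80. HLA-DRA at 5.01 in Sharp1 cells read below the median probe set (5.41), and HLA probe sets can bind related HLA transcripts, so the sizes of single HLA changes are uncertain.

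Trefoil and mucosal secretory genes fell in Sharp1 cells for 6 of 13 members and rose for SPINK1 alone, and in shHIF cells 4 rose and 3 fell. TFF3 fell in both, by 1.71 and 0.70, whereas the gastrokine GKN2 fell by 1.84 in Sharp1 and rose by 0.52 in shHIF, and SPINK4 fell by 1.21 and rose by 1.42. GKN2 read 3.73 in Sharp1 cells, below the median probe set, so the size of its fall rests on a dim reading. NRF2 targets of oxidative stress defence rose for 10 of 16 and fell for 2 in shHIF cells, and in Sharp1 cells 4 rose and 5 fell. The rises in shHIF ranged from 0.10 for FTL to 0.80 for HMOX1, and NQO1 and ME1 differed by -0.27 and -0.41. Of all genes, 30.8% were called in shHIF cells, and 55.6% in the brightest decile of expression, so the count alone does not set this list apart. The aldo-keto reductases AKR1C1, AKR1C2 and AKR1C3 fell by 1.26, 1.27 and 1.84 in Sharp1 and rose by 1.30, 1.17 and 0.86 in shHIF, and signals of these near-identical paralogues were not separated here. Activin subunits diverged in Sharp1 cells: INHBA rose by 2.00 beside INHBE, and INHBB fell by 1.66. ID1, another helix-loop-helix inhibitor, rose by 1.15. The mitochondrial gene ND6 rose by 1.59 in Sharp1 and fell by 0.34 in shHIF.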
